A study of Mus musculus with 6 samples.

How the data were processed

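RNA was measured in erythrocytes of 6 individual BALB/c male mice, 3 heterozygous for the C587R missense allele of Nxf1 and 3 wild-type littermates. Per the labels' protocols, blood was taken by cardiac puncture, the red cells were pelleted through Ficoll and washed, and each suspension was checked by flow cytometry for platelets, CD45-positive cells and nucleated cells before lysis. Polyadenylated RNA was made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Each library came from a separate animal, so the replicates are biological.

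The deposited files hold raw counts per gene, 1 file per library, as whole numbers with no normalization, per the file headers and the values. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Subread and featureCounts and the genome build was mm10. The versions of Subread and featureCounts, the annotation and the strand setting were not given in the sources used here. Reads from a gene and from an overlapping or antisense partner therefore cannot be told apart in these counts. Counts of near-identical copies, such as the Mup genes, Serpina1b and Serpina1c, and the paired alpha and beta globin genes, depend on how multi-mapped reads were handled and are uncertain one by one.

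Each file listed 27179 genes by Entrez number, of which 25293 were given a symbol (25275 from a RefSeq gene table and 18 from GENCODE). The 1886 genes without a symbol took 1.39% of all counts and stayed in the tests. No count was seen in any library for 10783 genes. Gene positions came from RefSeq annotation of the same build. Globin transcripts took most counts, and 1627997 to 1877571 counts per library were left for all other genes. A count of 0 in a library allowed up to 3 counts, which was 0.190 to 0.205 CPM (counts scaled to a common library total) of the total count. Shares of single libraries carry 95% Wilson intervals. Intervals and floors cover counting error only, since the reads had no molecular identifiers.

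The main comparison was edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (robust), TMM scaling, filterByExpr by group, genotype as the only term, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of its F value. Printed CPM were scaled with TMM factors unless a share of total counts is named. Folds of genes with 0 wild-type counts were computed against a floor of 3 counts over the group, and with 1 to 3 wild-type counts the ratio has an exact binomial interval. Both used library totals multiplied by TMM factors, so they differ from the plain ratio of the printed counts. Single values per library were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

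Before the data were examined, 23 pathway lists and 9 lists of other cells or stages were fixed, with 917 entries of which 914 matched a gene. Lists with at least 3 tested members were compared by camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. Fry was planned beside it and asks whether members change, without setting them against the other genes. The rule for named genes was also fixed then. It took Nxf1, the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 5 that moved the same way in all 3 batch pairs (predicted models, genes without a symbol and pseudogenes left out), and up to 4 members with the smallest p per list. It also took the 4 globins and the 5 genes with most counts, the 2 most abundant markers per list of other cells, and up to 4 called genes within 10 Mb of Nxf1. Genes named outside this rule are said to be so. Some genes that the rule took are not reported here. Lists for hepatocytes, kidney, exocrine pancreas, heart muscle, skeletal muscle, lung, intestine and adipose tissue were written after the main comparison had been seen.

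The labels give a batch number, and each of the 3 numbers is shared by 1 mutant and 1 wild-type library. That label pairs the libraries. The correlations of same-batch libraries, as deviations from their group means across genes, were −0.116, −0.0855 and −0.0439. The comparison was repeated with batch as a term. Other alternatives were RLE scaling, total counts without scaling factors, removal of globin genes before scaling, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, and leaving out each library or each batch. Fits without the hepatocyte and pancreas lists, and without genes of 3 or fewer wild-type counts, were added after seeing the data.

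The tests were run on simulated counts for the 2823 genes tested, with 200 of them changed. For mutant against wild type, edgeR recovered 10% of changes of 1.5-fold, 26% of 2-fold, 92% of 4-fold and 100% of 8-fold, and 7.32% of its calls were unchanged genes. DESeq2 recovered 6%, 14%, 80% and 100% of the same sizes, and 2.91% of its calls were unchanged genes. That share was 7.63% for limma-voom and 9.52% for edgeR with batch as a term. Camera called 0 of 30 unchanged lists and called the raised list (adjusted p = 2.35e-09). The simulated genes were drawn independently, so this does not show how camera behaves on lists whose members move together. In the real data the estimated correlation was 0.41 for the mitochondrial list and 0.80 for the T and NK cell list.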

Results

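The study compared the transcripts of circulating red cells from mice carrying 1 copy of the C587R allele of Nxf1, which encodes the main export receptor for messenger RNA, with those of wild-type littermates. There were 3 mutant and 3 wild-type libraries, each from 1 male, and each of 3 batches held 1 of either genotype. Total counts ran from 14636739 to 15790336 per library.

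Nxf1 (Entrez gene 53319, chromosome 19, 8757103 to 8770910 in mm10) was close to the detection limit in these cells. Its counts were 9, 7 and 11 in the mutants and 15, 10 and 20 in wild type, or 0.708 ± 0.118 and 0.809 ± 0.211 CPM (SD, n = 3 each). The log2 fold change of −0.21 (SE 0.38) did not pass the test (edgeR adjusted p = 0.850; exact permutation p = 0.6, n = 3 each). With total counts, where the median of all genes was −0.53, it was −0.69 and did not pass either (edgeR adjusted p = 0.246). At this depth no difference in Nxf1 level was detectable, and the counts per gene do not show which allele was transcribed.

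Globin transcripts filled both kinds of library. They took 89.1% ± 0.197 of counts in the mutants and 88.6% ± 0.409 in wild type (SD, n = 3 each), with single libraries from 88.1% (95% Wilson interval 88.1 to 88.1) to 89.3% (89.2 to 89.3). The mutant share was 0.519 points higher, and higher by 0.384, 0.403 and 0.768 points within the 3 batches. The exact permutation test gave p = 0.1 (two-sided, n = 3 each), the smallest value this design allows. The ratio of beta globin (Hbb-bs and Hbb-b1) to alpha globin (Hba-a1 and Hba-a2) counts, which does not depend on scaling, was 0.799 ± 0.00450 in the mutants and 0.739 ± 0.0258 in wild type, without overlap (exact permutation p = 0.1, n = 3 each). Among the beta genes, the ratio of Hbb-bs to Hbb-b1 was 1.11 ± 0.0301 against 1.04 ± 0.0295 (exact permutation p = 0.1, n = 3 each). The ratio of Hba-a2 to Hba-a1 was 1.33 ± 0.0151 against 1.33 ± 0.0157 (exact permutation p = 0.6, n = 3 each). Both ratios within a pair depend on how reads of near-identical copies were assigned. They do not show the levels of single globin genes. Alas2, the first enzyme of erythroid heme synthesis, was the most abundant gene after these globins, and its log2 fold change was 0.41 with TMM scaling and −0.10 with total counts, neither past the test (edgeR adjusted p = 0.201 and 0.163). With TMM scaling Alas2, Hba-a1, Hba-a2 and Hbb-b1 passed without mutant library 3 (0.61, 0.71, 0.70 and 0.77, edgeR adjusted p 0.000204 to 0.00218) or without batch 3 (0.62, 0.69, 0.68 and 0.74, adjusted p 0.00137 to 0.00964). The 3 globins of these also passed with no filter on low counts, and Hbb-b1 with DESeq2. With total counts and all libraries, Hba-a1 and Hba-a2 had log2 fold changes of −0.038 and −0.042 (edgeR adjusted p = 0.353 and 0.291). The 4 most abundant globins took 88.1% to 89.2% of counts in every library. The globin rises therefore depend on the scaling factors and do not show a rise of this size in the share of counts.

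**Figure D1:**
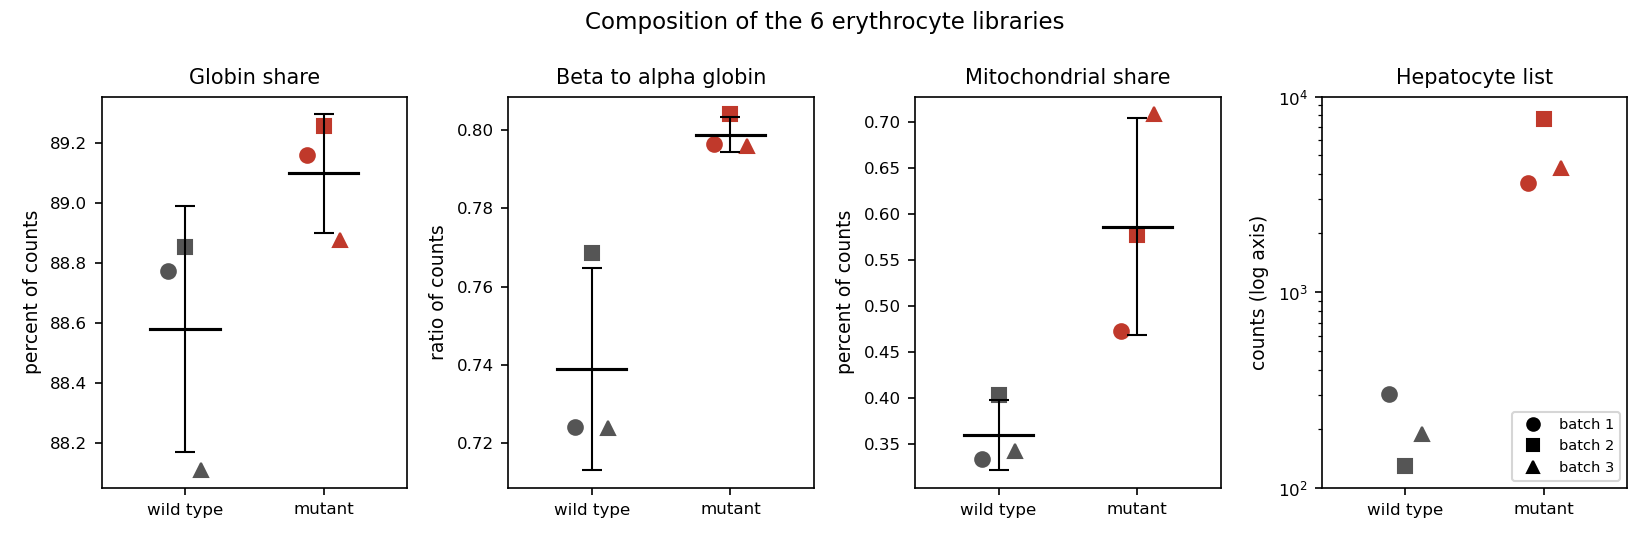
Each point is 1 library and its shape marks the batch; wild type is grey and mutant red. The panels show, from left to right, globin transcripts as percent of counts, the ratio of beta to alpha globin counts, mitochondrially encoded transcripts as percent of counts, and counts in the hepatocyte list on a log axis. Lines and bars in the first 3 panels are means and SD, whose axes do not start at 0. The 3 mutants lie above the 3 wild-type libraries in every panel, from 3611 to 7667 hepatocyte-list counts against 130 to 303.

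The libraries separated by genotype group, and the genes tested included the hepatocyte transcripts described below. Of 2823 genes tested, 169 were higher and 30 lower in the mutants (edgeR, adjusted p under 0.05), and 168 of the 169 and all 30 moved the same way in the 3 batches. The first principal component held 67.6% of the variance and placed the mutants between −32.9 and −19.2 and wild type between 24.7 and 26.4. The largest rises were transcripts best known from the liver. Alb, serum albumin, had 2426 counts over the mutants and 1 over wild type, a TMM-scaled count ratio of 3473 (95% interval 623 to 137233). Mup7, Mup2 and Mup8 (major urinary proteins), Apoa1 (the main apolipoprotein of HDL) and the antitrypsin genes Serpina1b and Serpina1c had 0 counts in wild type. With TMM-scaled library totals they were at least 361-, 263-, 255-, 241-, 182- and 179-fold higher. With total counts these bounds would be lower, since wild type had the higher TMM factors. Cyp2e1, a cytochrome P450, had 458 counts against 1, a TMM-scaled ratio of 656 (117 to 25953). Trf (transferrin) and Apoe (apolipoprotein E) had log2 fold changes of 5.26 (SE 0.68) and 4.58 (SE 0.34), with adjusted p of 0.00752 and 1.09e-06. The call of Mup2 was lost without mutant library 1 (edgeR adjusted p = 0.154) or batch 1 (0.150), and that of Cyp2e1 without wild-type library 3, batch 1 or batch 3 (adjusted p = 0.112, 0.112 and 0.0778).

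The hepatocyte list, written after this comparison had been seen, had 113 members. Of the 67 tested, 62 were higher and 0 lower, and its counts were 3611, 7667 and 4329 in the mutants and 303, 130 and 189 in wild type. The wild-type counts were uneven between members, as Hp and Ttr show, named after their values were seen. Hp had 84, 61 and 82 counts in wild type and 83, 112 and 116 in the mutants. Ttr had 90, 0 and 0 in wild type and 85, 273 and 133 in the mutants. Among the 169 higher genes, 61 had 0 counts in wild type and 20 had 1 to 3. Without the hepatocyte and exocrine pancreas lists 102 genes were higher and 22 lower. That fit still held Apoe, which is not on the hepatocyte list. Without genes of 3 or fewer wild-type counts 81 were higher and 19 lower. Exocrine pancreas transcripts had 436 counts in wild-type library 1, with all 17 members of that list seen, and at most 3 counts in each of the other libraries.

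Mitochondrially encoded transcripts rose together. All 14 members tested were higher, with log2 fold changes from 0.76 to 4.32 and a list median of 2.12. All 14 were also called when adjusted over the list alone. mt-Nd2, mt-Nd6, mt-Nd1 and mt-Nd5, which encode subunits of respiratory complex I, rose by 4.17 (SE 0.21), 3.51 (SE 0.22), 3.24 (SE 0.20) and 3.02 (SE 0.19) on the log2 scale, with adjusted p of 3.28e-10, 2.33e-09, 2.33e-09 and 2.33e-09 (edgeR). mt-Nd2 went from 11.9 ± 0.610 to 215 ± 58.6 CPM (SD, n = 3 each). The genome is compact and mt-Nd6 (MT, 13552 to 14070) overlaps the end of mt-Nd5 (MT, 11742 to 13565), so their counts are not fully separate. The ribosomal RNA genes mt-Rnr1 and mt-Rnr2, named after their values were seen, had the smallest changes and were the only members not called with total counts (log2 0.30 and 0.26, adjusted p = 0.0830 and 0.0787). Their calls were lost without mutant library 2 or wild-type library 3, and for mt-Rnr2 also without mutant library 1 (adjusted p 0.0706 to 0.0786 and 0.0546 to 0.103). As a share of all counts, mitochondrially encoded transcripts made up 0.586% ± 0.118 in the mutants and 0.359% ± 0.0382 in wild type, higher in the mutant in all 3 batches (exact permutation p = 0.1, the smallest possible, n = 3 each). Camera gave an adjusted p of 3.81e-19 for the list, and adjusted p = 0.491 with an estimated correlation. Fry gave an adjusted p of 0.00290. The hepatocyte transcripts were present in these same 3 libraries.

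**Figure D2:**
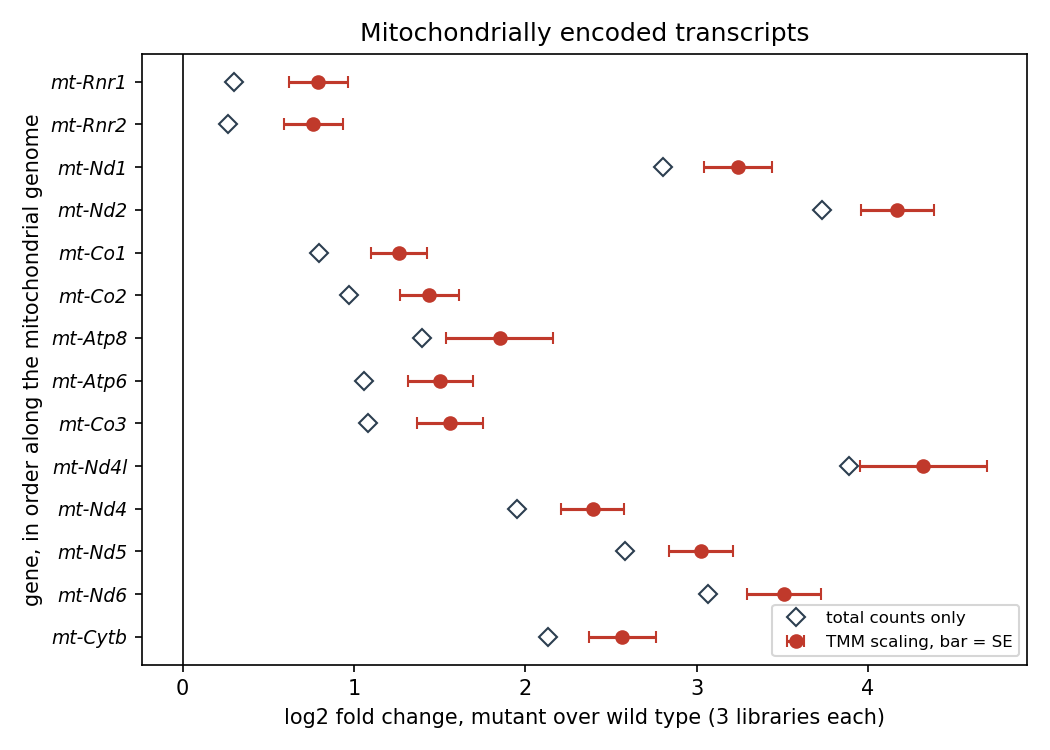
Log2 fold change of each mitochondrially encoded gene, mutant over wild type (x axis), with genes in order along the mitochondrial genome (y axis). Red points are TMM-scaled values with SE, and open diamonds the values with total counts. All 14 points lie above 0 under both scalings, from 0.76 to 4.32 and from 0.26 to 3.89.

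Outside the hepatocyte and mitochondrial lists, 68 higher genes had more than 3 counts over wild type, with log2 fold changes from 0.53 to 4.58 and a median of 0.87. The highest value was that of Apoe, named above with the liver transcripts but absent from the hepatocyte list. These genes are therefore not free of transcripts known from liver. With total counts 14 of these 68 were still higher. Of 32 cytosolic ribosomal protein genes tested, 5 were higher, 0 lower and 27 not called (7 higher when adjusted over the list alone, and 0 higher and 1 lower with total counts). Among them were Rplp1 (log2 0.84, SE 0.17), Rplp0 (0.77, SE 0.16) and, named after its value was seen, Rplp2 (0.81, SE 0.19). Single members were higher in other lists. E2f2, a cell cycle transcription factor used in erythroid maturation, had a log2 fold change of 0.83 (SE 0.17). Ube2l6, an enzyme that conjugates Isg15 and is abundant in red cells, had 0.80 (SE 0.17), Ran, the GTPase of nuclear transport, 0.82 (SE 0.21) and Ndufa1, a nuclear-encoded complex I subunit, 0.86 (SE 0.18). Their edgeR adjusted p were 0.00256, 0.00445, 0.0233 and 0.00428. All of these named genes but Ube2l6 lost their call with total counts, where the median of all genes was −0.53 and their values were 0.26 to 0.35. That of Ube2l6 was 0.29 (adjusted p = 0.00873), and its call was lost without mutant library 1 or 2 or wild-type library 3 (adjusted p 0.0509 to 0.0545). Calls also ended without mutant library 1 or wild-type library 3 for Rplp0 (0.0612 and 0.0561), without these or mutant library 2 for Rplp2 (0.0508 to 0.0948), without wild-type library 3 for Ndufa1 (0.0710), and without any library but mutant 3 for Ran (0.0561 to 0.115). Without batch 2 all of these named genes but Ndufa1 lost their call, Rplp1 and E2f2 included (0.0600 and 0.0850), and against a fold of 1.5 all 7 did (0.358 to 0.578).

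Of the 30 lower genes, whose log2 fold changes ran from −2.44 to −0.58, 5 met the rule for naming. AI662270, a long non-coding RNA (Entrez gene 100043636, chromosome 11, 83223576 to 83226584), fell by 1.30 on the log2 scale (SE 0.19, edgeR adjusted p = 9.88e-05), from 28.9 ± 6.67 to 11.7 ± 0.254 CPM (SD, n = 3 each). Rec114, a gene known from meiotic recombination (Entrez gene 73673), fell by 1.10 (SE 0.18, adjusted p = 0.000319), from 58.1 ± 11.8 to 27.2 ± 3.38 CPM. H2aj (histone H2A.J), Cd24a (a surface antigen of immature red cells) and Pttg1 (securin) fell by 0.67, 0.63 and 0.58 on the log2 scale, with adjusted p of 0.0305, 0.0284 and 0.0385 (edgeR). With batch as a term, 60 genes were lower and 194 higher, with 29 of the 30 and 168 of the 169 called again. DESeq2 called 11 genes lower and 177 higher, and H2aj, Cd24a and Pttg1 were not among them (adjusted p = 0.0872, 0.0823 and 0.109). These calls were also lost without any 1 library other than wild-type 1, with adjusted p of 0.111 to 0.224, 0.121 to 0.303 and 0.113 to 0.250 (edgeR).

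The split between rises and falls depended on scaling. TMM factors were 0.720, 0.780 and 1.06 in the mutants and 1.23, 1.11 and 1.23 in wild type. With TMM 84.9% of the called genes were higher. With total counts 115 were higher and 245 lower, 31.9% higher, and the median log2 fold change of all genes was −0.53 in place of −0.06. Of the genes called with TMM, 111 of the 169 and all 30 kept their direction and call. Genes with at least 10 counts numbered 2409 ± 338 in the mutants and 3413 ± 678 in wild type (exact permutation p = 0.2, n = 3 each).

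Of the 32 lists, 30 had 3 or more tested members and 2 passed camera, the mitochondrial list and the list of T and NK cell genes. That list was lower, on 3 tested members. Gzma (granzyme A) fell by 2.10 on the log2 scale (SE 0.45, edgeR adjusted p = 0.00428) and Tcf7, a T cell transcription factor, by 2.00 (SE 0.47, adjusted p = 0.00913). Lck had a log2 fold change of −0.88 (adjusted p = 0.277), and −0.24 without batch 3 and −0.50 without wild-type library 3. Counts were few, 14 against 88 for Gzma and 10 against 59 for Tcf7. The camera adjusted p of the list was 0.0208, and adjusted p = 0.999 with an estimated correlation, 0.214 with total counts and 0.0617 without wild-type library 3. Fry gave an adjusted p of 0.218 for this list. The call of Gzma was lost without mutant library 3 (edgeR adjusted p = 0.0617), without batch 3 (log2 −1.46, adjusted p = 0.212) and with DESeq2 and batch as a term (adjusted p = 0.122). That of Tcf7 was lost without mutant library 2 or 3 or wild-type library 3 (adjusted p = 0.0580, 0.0635 and 0.119) and with DESeq2 (adjusted p = 0.0642, and 0.363 with batch as a term). Without batch 2 or 3 it was also lost (edgeR adjusted p = 0.0663 and 0.134). Adjusted over the list alone, 2 members were lower.

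The other 28 lists did not pass (camera adjusted p 0.103 to 0.997), and 20 lists had no called member. The mRNA export list, which includes Nxf1, had 0 of 11 members called and a median log2 fold change of −0.21. Its members with the smallest p were the SR proteins Srsf7 and Srsf3 (log2 −1.06 and −0.73, edgeR adjusted p = 0.240 and 0.273). Srsf7 had −0.62 without batch 1 and −0.40 without wild-type library 1, and Srsf3 −0.38 without wild-type library 3. Of 24 splicing factors 1 was called, Srsf6 (log2 −1.51, SE 0.44, adjusted p = 0.0464), on 20 counts against 83 (0 when adjusted over the list alone). Of 21 translation factors 1 was called, Eif1 (log2 −0.85, SE 0.24, adjusted p = 0.0422), and 1 was lower and 1 higher with batch as a term or when adjusted over the list alone. With total counts 3 splicing and 4 translation factors were lower. DESeq2 called neither Srsf6 nor Eif1 (adjusted p = 0.140 and 0.113). The call of Srsf6 was lost without any 1 library other than mutant 2 (edgeR adjusted p 0.0523 to 0.263), its log2 fold change being −0.91 without batch 1 and −2.43 without batch 2, and that of Eif1 without any other than wild-type 1 (0.0616 to 0.278). Of 8 globins tested 1 was called (4 adjusted over the list alone), Hbb-bs (log2 0.63, SE 0.19, adjusted p = 0.0492), a call lost with batch as a term (adjusted p = 0.0563) and without any 1 library other than mutant 3 (0.0876 to 0.287). The globin list had a median of 0.48 with TMM and −0.03 with total counts, and the ribosomal protein list 0.23 and −0.29.

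Of 25 red cell membrane and skeleton genes, 0 were called and the median log2 fold change was −0.20, while 3 were lower with batch as a term and 5 with total counts. Ermap, an erythroid membrane protein, missed the threshold (log2 −1.07, edgeR adjusted p = 0.0516) and passed with batch as a term (0.00459). The same held for Trim10, an erythroid ubiquitin ligase (log2 −0.72, adjusted p = 0.0711 and 0.00521), Isg15, an interferon-induced modifier (−0.64, 0.0595 and 0.0177), and the non-coding RNA Lockd (−0.75, 0.0588 and 0.0177). DESeq2 with batch as a term called none of these (adjusted p = 0.321, 0.0996, 0.364 and 0.451 in this order). The other membrane genes that passed with batch as a term were Stom (stomatin, log2 −0.92, edgeR adjusted p = 0.139 and 0.0122) and, named after its values were seen, Kcnn4 (a potassium channel, −1.07, 0.392 and 0.00948), and DESeq2 with the term called neither (0.543 and 1.00). The batches did not move alike. In batch 1 the log2 differences of Ermap, Stom, Kcnn4, Isg15, Lockd and Trim10 were −0.0050, 0.33, 0.50, 0.041, −0.11 and −0.41, and all 6 genes passed without batch 1 or wild-type library 1 (edgeR adjusted p 0.000712 to 0.0305). Without batch 2 they had −0.75, −0.56, −0.61, −0.42, −0.33 and −0.54, and 0 passed (0.411 to 0.710). Kcnn4 had −0.70 without mutant library 2 and −0.68 without wild-type library 3, and Lockd −0.45 without wild-type library 2. Of the non-coding RNA list 0 of 5 members were called (2 lower when adjusted over the list alone) and the median was −0.45. The early erythroid list had a median of −0.46 on 5 members, 0 of them called (1 lower when adjusted over the list alone). Among blood cell lists, 0 of 7 B cell genes (median −0.67), 0 of 5 dendritic and antigen presentation genes (−0.39, 1 lower when adjusted over the list alone) and 0 of 12 neutrophil genes (0.20) were called. With batch as a term, and also with total counts, 2, 1, 1 and 1 members of the non-coding RNA, early erythroid, B cell and dendritic lists were lower. With batch as a term Cd74 and Lyz2 passed in opposite directions (log2 −0.82 and 0.91, edgeR adjusted p = 0.0158 and 0.00138 with the term, 0.0645 and 0.0711 without). DESeq2 with the term called neither (adjusted p = 0.531 and 0.0520), and without it called Lyz2 alone (0.0179). By batch Cd74 was −0.66, −0.034 and −1.61, and it had −0.27 without batch 3 and −0.52 without wild-type library 3 (edgeR adjusted p = 0.685 and 0.433). Lyz2 was 1.52, 0.39 and 0.56 by batch, and had 0.55 without batch 1 and 0.60 without mutant library 1 (0.291 and 0.277). Both passed without batch 2 (0.0318 and 0.0223), Cd74 also without wild-type library 2 (0.0352) and Lyz2 without mutant library 2 (0.00513).

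Genes around Nxf1 were not called more often than others. Within 10 Mb, 1 of 70 tested genes was called, against 192 of 2718 elsewhere (odds ratio 0.191, 95% interval 0.00474 to 1.11, two-sided Fisher's exact p = 0.0888). That gene was Mpeg1 (chromosome 19, 12460770 to 12465285), a perforin-like protein of phagocytes, with a log2 fold change of 0.84 (SE 0.25, edgeR adjusted p = 0.0489), not called with total counts (adjusted p = 0.380) or without mutant library 2 or 3 or wild-type library 2 or 3 (0.0508 to 0.269), with a log2 fold change of 0.49 without batch 3.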

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

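Fits without the hepatocyte and exocrine pancreas lists, fits without genes of 3 or fewer wild-type counts, the blocked set test with an estimated correlation, and the alternatives for the beta to alpha and mitochondrial shares were chosen after the data were seen. The number of genes called, 199, became 360 with total counts, 464 with no filter (16396 genes tested), 115 at a mean count of at least 50 (666 tested), 116 against a fold of 1.5, 124 without the organ lists and 100 without genes of 3 or fewer wild-type counts. Higher genes, 169, became 382 with no filter, 66 at a mean count of 50, 108 against a fold of 1.5, 102 without the organ lists and 81 without the near-absent genes. Lower genes, 30, were the least stable: 19 with RLE scaling, 245 with total counts, 82 with no filter, 49 at a mean count of 50, 11 with DESeq2, 8 against a fold of 1.5 and 19 without the near-absent genes. The replicate block gave 60 lower genes, the block without globins 60, and the block with DESeq2 3. Without batch 2 there were 19 and without batch 3 there were 3. Leaving out single libraries gave 8 to 77: 14, 15 and 8 without mutant 1, 2 and 3, and 77, 26 and 11 without wild-type 1, 2 and 3. The stricter filter and the omitted lists test fewer genes. The fit with total counts differed from the main fit only by leaving out the TMM factors. The cause of the other shifts was not tested.

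Nxf1 was called in no fit. Its log2 change ranged from −0.35 to 0.011 over left-out libraries, turning positive without wild-type library 3, and was 0.079 without batch 3; it was not tested at a mean count of 50. Of 30 lists, 2 passed; 1 passed with total counts, 6 of 32 with no filter, 0 with an estimated correlation and 0 with that and the replicate block, and 1 to 4 over left-out libraries (1 without wild-type 3, 4 without wild-type 1 or 2). Signs turned with total counts for Hba-a2 (−0.042), Hba-a1 (−0.038), Alas2 (−0.10), the globin list (−0.030), the ribosomal protein list (−0.29) and the neutrophil list (−0.25), and with no filter for the ribosomal protein list (−0.13) and the early erythroid list (0.48). The turns with total counts came with leaving out the TMM factors, which moved the median of all genes from −0.06 to −0.53. The cause of the turns with no filter was not tested. Over all alternatives of the named genes, 907 values kept direction and call, 160 lost the call, 60 gained it and 3 reversed. Besides the losses given with the results, leaving out a batch ended the calls of mt-Rnr1, Rplp0, Rplp2, Ube2l6 and Ran (batch 1), mt-Rnr2 (1 and 2), Hbb-bs (1 and 2), H2aj, Pttg1 and Eif1 (each), Cd24a and Mpeg1 (2 and 3) and Srsf6 (1 and 3), a fold of 1.5 ended all of these, and DESeq2 with the block ended those of H2aj, Cd24a, Pttg1, Eif1, Srsf6 and Mpeg1. The replicate block in edgeR changed no other call of a gene printed here, and no camera call of a list with the preset correlation. Of the genes that the naming rule took and that are not printed, 6 gained a call with it and 0 lost one. Interferon, glycolysis and iron lists, with 0 called, had 2, 1 and 1 lower members with it. mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6, Alb, Apoa1, Trf, Apoe, AI662270 and Rec114 were called under every alternative that tested them. The globin share stayed 0.284 to 0.656 points higher in the mutants over left-out libraries. Changes under 2-fold were rarely detectable at this depth, as the simulated counts showed.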

Other observations

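All tests of causes in this part were chosen after the results they bear on had been seen. The fit with total counts, which several of them use, was planned. The mitochondrial rise was uneven between genes. The 6 tested genes of complex I subunits had log2 fold changes from 2.39 to 4.32 (median 3.37), and the other 8 genes from 0.76 to 2.57 (median 1.47). This grouping was chosen after the values were seen, so no test of it is given. mt-Nd4l and mt-Cytb mark the upper end of either group.

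Counts in the kidney list were 1, 3 and 6 in the mutants and 2, 3 and 4 in wild type, and in the heart muscle list 5, 3 and 9 against 9, 10 and 4. The skeletal muscle list had 8, 5 and 3 against 7, 7 and 9, the intestine list 6, 13 and 7 against 23, 0 and 6, the lung list 26, 21 and 23 against 26, 15 and 15, and the adipose list 353, 409 and 381 against 383, 348 and 405. Cyp2f2 of the lung list (44 counts against 0, at least 21.0-fold with TMM scaling) and Car3 of the adipose list (126 against 1, a TMM-scaled ratio of 180 with a 95% interval of 31.8 to 7180), named after their values were seen, were higher in the mutants. Both are also known from mouse liver.

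Hepatocyte transcripts in the mutants were the most visible pattern. Reads passed among the 6 libraries would need a source among them, but the highest Alb count was only 2.32 times the third highest, and wild type held 1 Alb count against 2426. Liver RNA or cells mixed into the mutant samples may account for it and remain open. Of 102 list members with 10 or more counts, 94.1% were higher in every mutant than in every wild-type library, but the list was written for this pattern and a genotype effect would give the same order, so this share does not decide. The nucleated-cell check of the preparation bears on whole hepatocytes and not on free RNA. The hepatocyte list took 0.0238% to 0.0503% of mutant counts, and the detection limit of that check is not given here. The check therefore does not tell whole cells from free RNA. A source outside these libraries and the genotype itself also remain open and untested.

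The mitochondrial rise stayed with total counts, where the list median was 1.67 with 12 of 14 members called, which argues against the choice of scaling as its cause. Liver RNA could contribute. The mitochondrial excess was 5.04, 4.44 and 12.4 counts per hepatocyte-list count in mutants 1, 2 and 3. It was highest in mutant 3, while hepatocyte-list counts were highest in mutant 2. What liver RNA would give per hepatocyte count was not measured. This excess per hepatocyte count differed 2.78-fold between the mutants, above the 95th percentile of 1.83 for 39 single hepatocyte genes. Moving each mutant by 2 wild-type SD brings it to 1.61, so this cannot be told apart with 3 animals. Less mature red cells, which keep mitochondria, also remain open: the early erythroid list had a median of −0.46 (bootstrap SE 0.66) with 2 members above 0 and 3 below. Genotype is the untested biological alternative.

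With total counts the median log2 fold change of all genes was −0.53. It was −0.58 in the 2163 tested genes with mean counts under 50, −0.45 at 50 to 1000, −0.20 at 1000 to 100000 and 0.013 above that. In the class under 50, the mutant to wild-type ratio of the share of counts was 0.469, 0.830 and 0.849 in batches 1, 2 and 3. Fewer white cells would lower their lists and spare red cell genes. The T and NK cell, B cell and dendritic lists (−2.48, −1.18 and −0.93) were below all genes. The monocyte and neutrophil lists (−0.34 and −0.25) were not, and neither was the platelet list (−0.51). Nor were all red cell genes spared: the membrane and skeleton list had a median of −0.69 (bootstrap SE 0.11), with 24 of 25 members below 0. The lists of erythroid regulators and of reticulocyte maturation had medians of −0.53 and −0.45. The heme synthesis and globin lists were lowered less, with −0.27 and −0.03. Fewer lymphocytes stay open for the T and NK cell and B cell lists, whose 10 members had a median of −1.33 (bootstrap SE 0.23). The check for CD45-positive cells does not decide this, since its detection limit is not given here. Summed counts of T and NK cell genes (median −2.48) were below all genes in each batch (log2 −1.30, −1.42 and −2.32 against −0.82, −0.57 and −0.20). Those of B cell genes (median −1.18) were below in batch 3 alone (−0.30, −0.15 and −2.22). There wild-type library 3 held 643 B cell list counts against 282 and 268 in the other wild-type libraries. A few genes taking more of the counts would account for −0.13, the log2 ratio of the share outside the 8 genes with a mean count over 100000, and between −0.19 and −0.07 within batches. The shift was −0.42 (bootstrap SE 0.017) in the shortest 941 genes, −0.56 (0.018) in the middle and −0.61 (0.014) in the longest, which argues against loss of long transcripts as the whole cause but leaves it open for the −0.19 between longest and shortest, which was −0.20 (SE 0.027) among genes with mean counts under 50 and −0.06 (SE 0.062) at 50 to 1000. What lowers the other transcripts was not found, and a difference in red cell age or in RNA content by genotype was not tested.

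For the count of called genes, the 6 libraries allow 10 splits into 3 and 3, and 1 of them, the real one, gave as many as 199 genes; the highest of the others gave 0 (31 to 157 genes at an unadjusted p under 0.05, edgeR). Of these splits 4 part all 3 batches, and the 3 of these other than the real one also gave 0 (55 to 127 at an unadjusted p under 0.05); the other 6 put both libraries of a batch on 1 side and gave 0 as well (31 to 157). With 10 splits no share under 0.05 can be reached.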
